A study of Haloarcula hispanica ATCC 33960 with 32 samples.

How the data were processed

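The series measured RNA by sequencing in the haloarchaeon Haloarcula hispanica, in the parent strain DF60 and in strains AKS133 and AKS319, which carry a further deletion of trmB. TrmB proteins are archaeal transcription regulators of sugar metabolism. All of these strains are labelled as lacking pyrF, which encodes orotidine 5'-phosphate decarboxylase of uracil synthesis and serves as a genetic marker, and the media contained uracil. Per the labels' protocols, cultures were grown to stationary phase in a rich medium with glucose, washed, and moved into Hh-CA medium with 0.1% glucose or without it, and cells were collected after 24 h. Ribosomal RNA was removed with a PanArchaea riboPOOL kit and stranded libraries were made with a KAPA kit, per the labels' protocols.

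The authors deposited raw read counts per gene in a table of the whole series, with 3863 rows and 32 libraries, and every column matched 1 library by its name. The rows carry locus tags alone. The submitters' processing notes name Trim Galore 0.4.3, cutadapt 2.3, FastQC 0.11.7, Bowtie2 2.3.5.1, SAMtools 1.10, featureCounts 2.0.1 and DESeq2 1.34.0. The genome build, the annotation, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. Rows that overlap, lie antisense to each other or resemble each other closely could therefore share reads, and no copy number was checked. Per the labels, each library also has a percent of read pairs mapped and a count of fragments mapped to pyrF. These label values were not altered.

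No annotation was used here, so locus tags could not be paired with gene names, chromosome positions or functions. The exception is pyrF: its fragment counts in the labels equal the counts of row HAH_RS10105 in 32 of 32 libraries, and 1 row of the table has this property. The row of trmB could not be looked up by name. The 29 gene lists fixed before the data were examined were defined by gene symbol and product, so their members could not be matched and no list test was run. At most 2 locus tags per direction are named for each comparison.

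Libraries were grouped by strain, medium and year from the labels. The labels mark 29 libraries as used for differential expression: 15 of DF60, 6 of AKS133, all from 2021, and 8 of AKS319, all from 2022. These 29 entered every comparison. The other 3 libraries, replicate B of DF60 without glucose in 2021 and 2 libraries of reference RNA from strain DF70, labelled as wild type, were kept for description. Each group's libraries carry replicate letters. The growth protocol speaks of single colonies but does not tie the letters to them, so p-values measure the spread between these libraries, part of which may be technical.

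Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling factors, filterByExpr at its default minimum count of 10 over the 4 genotype and glucose cells, and robust quasi-likelihood fits (glmQLFit and glmQLFTest). The model held the 4 cells and the 3 year and flowcell levels, and 3841 rows were tested. The 5 comparisons were mutant against parent without glucose, the same with glucose, glucose against no glucose in the parent, the same in the mutant, and the difference of these glucose responses. A second model with 8 strain, medium and year groups compared the effect of the deletion between AKS133 and AKS319. Strain and year cannot be told apart in the mutants, so each mutant was set against parent libraries of its own year. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and calls with an absolute log2 fold change of at least 1 are given beside them. Standard errors were computed from the fold change and the F statistic. Counts-per-million values (CPM) were computed from each library's total count, without scaling factors, and are given as mean ± SD.

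Genes named in the text followed a rule fixed before the data were examined: the largest changes in each direction among called genes with a mean of at least 10 CPM and the same sign in fits of each year, of which the first 2 per direction are printed. The condition on years was not applied to the comparison of the mutant strains. HAH_RS07525 falls under this rule, and it is also described on its own because of its values. pyrF was planned to be described without a test, but its row entered the test across all rows and fell under the rule. Members of gene lists that the rule also named could not be matched. Principal components were computed from log2 CPM with a prior count of 2. Replicate libraries were compared with a chi-square statistic, and in 44 pairs of libraries of a group its ratio to the degrees of freedom lay between 25.9 and 5067. No pair was within sampling noise.

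The procedure was tested on simulated counts for 3841 genes drawn with the dispersion trend of the fit and with 67 genes changed by 2-fold in each comparison. It recovered 95.5% of those for mutant against parent without glucose and 98.5% with glucose. The figures were 98.5% for the glucose response of the parent, 98.5% for that of the mutant and 73.1% for the difference of the responses. Of 67 genes changed by 1.5-fold, it recovered 43.3%, 65.7%, 67.2%, 47.8% and 14.9% in these 5 comparisons.

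Alternatives fixed before the data were examined were DESeq2 size factors, no filter, DESeq2 1.42.0 as the test, year alone or no batch term, each year alone, the unused parent library added, AKS319 libraries with over 1000 pyrF fragments left out, a term for such libraries, a block for replicate letters, the deleted loci and their neighbours left out, and each library left out in turn. The row of trmB was not identified, so the deleted loci were taken as pyrF and HAH_RS07525, the latter chosen from its values. The block held strain, year and letter for the glucose responses and their difference, and year and letter for the other comparisons. Plain library totals, leaving out the parent libraries lettered C without glucose, and leaving out 6 abundant rows were added after the data were examined. Figures were drawn with Python 3.11.15.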

Results

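RNA was sequenced from Haloarcula hispanica cells that had spent 24 h in Hh-CA medium with 0.1% glucose or without it. The parent strain DF60 gave 15 of the analysed libraries, 7 without glucose and 8 with glucose. The trmB deletion strains gave 14, namely AKS133 in 2021 (2 without glucose, 4 with glucose) and AKS319 in 2022 (4 in each medium). Total counts ran from 12719797 to 37285906 per library over all 32 libraries. In a principal component analysis, the first component held 47% and the second 25.3% of the variance, and libraries separated by year as well as by medium. Mutant and parent libraries with glucose lay together within each year, while mutant libraries without glucose lay apart from the parent.

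**Figure D1:**
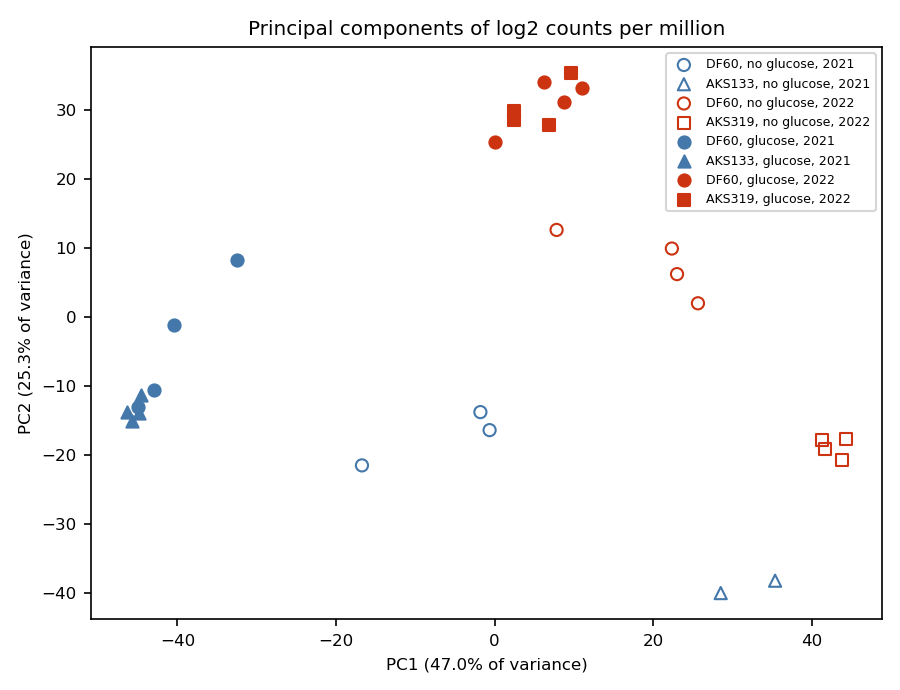
Principal components of log2 CPM values of the 29 analysed libraries, with the percent of variance on each axis. Circles are DF60, triangles AKS133 and squares AKS319; blue is 2021, red is 2022, open symbols lack glucose and filled symbols had it. The 6 mutant libraries without glucose have the 6 highest values on the first component.

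The levels of the deleted genes were examined first. pyrF (HAH_RS10105) was near the floor in the parent, with 29 to 153 counts per library over all 16 DF60 libraries. It was high in every AKS133 library, with 1928 to 20685 counts, although the strain is labelled as lacking the gene. In AKS319 it was high in 4 libraries (5077 to 11627 counts: replicates B and D with glucose, B and C without) and low in the other 4 (17 to 50 counts). The 2 libraries of reference RNA from DF70, labelled as wild type and taken from rich medium, held 5294 and 4589 counts. The table does not pair locus tags with gene names, so the row of trmB was not identified. HAH_RS07525 was the only row whose highest mutant level lay below 0.1 of its lowest parent level, a criterion set after the values were seen. It averaged 1.27 ± 0.739 CPM (SD, n = 14) in the mutants and 125 ± 18.8 CPM (SD, n = 15) in the parent, so the mutant mean was 1.01% of the parent mean. Of the 8 rows lying within 2 rows of pyrF or HAH_RS07525 in the table, 6 passed the test between mutant and parent without glucose and 0 with glucose. Without glucose 55% of all genes passed, and the log2 fold changes of the 8 rows ran from -2.36 to 1.1, so no local effect is shown.

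**Figure D2:**
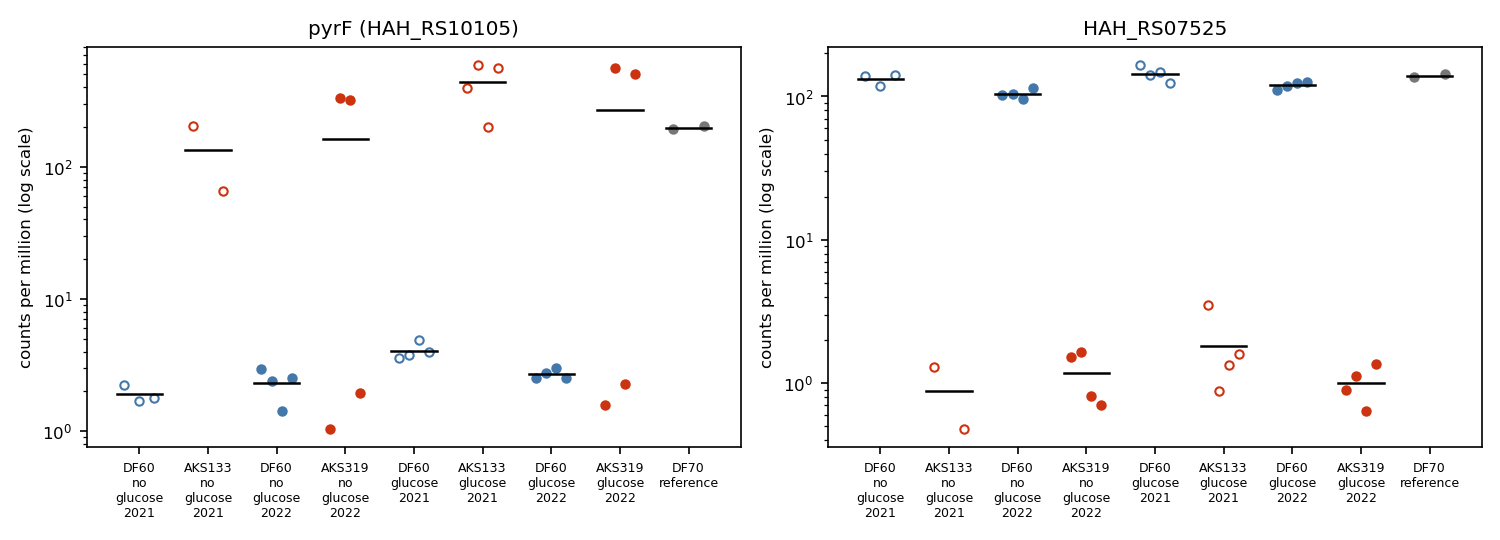
CPM values of pyrF and of HAH_RS07525 in each library on a log axis, by strain, medium and year; open circles are 2021, filled circles 2022, blue the parent, red the mutants, grey the reference RNA, and bars are group means. The mutants lie at 0.478 to 3.48 CPM for HAH_RS07525, and the AKS319 libraries fall into a high and a low set for pyrF.

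The first comparison asked which transcripts depend on trmB in cells without glucose. Without glucose, the mutants differed from the parent at many genes. HAH_RS06900 was lower, with a log2 fold change of -7.47 (SE 0.28, edgeR quasi-likelihood test, adjusted p = 4.84e-17). It stood at 1348 ± 250 CPM (SD, n = 3) in DF60 and 4.83 ± 0.12 CPM (n = 2) in AKS133 in 2021, and at 1132 ± 175 CPM (n = 4) in DF60 and 4.97 ± 0.59 CPM (n = 4) in AKS319 in 2022. HAH_RS07525 was lower, at -6.38 (SE 0.29, adjusted p = 1.79e-15). HAH_RS04465 was higher by 5.17 (SE 0.40, adjusted p = 2.64e-11), at 9457 ± 1815 CPM (n = 2) in AKS133 against 215 ± 52.0 CPM (n = 3) in the parent of that year, and at 5853 ± 561 CPM against 272 ± 105 CPM (n = 4 each) in 2022. pyrF was higher by 6.70 (SE 1.18, adjusted p = 3.11e-05), an average over AKS319 libraries with and without it.

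In all, 2113 of 3841 genes (55%) were called without glucose, 1049 higher and 1064 lower in the mutants, and 265 and 360 of them changed by at least 2-fold. The 2021 libraries alone called 2077 genes (1044 higher, 1033 lower) and the 2022 libraries alone 2253 (1030 higher, 1223 lower). Of these, 1590 and 1842 were among the 2113. Of the calls from both years together, 97.2% had the same sign in 2021 and 99.8% in 2022. Those calls rest on the same libraries, so such percentages, here and below, are partly built in. Across genes, which are not independent replicates, the log2 fold changes of the years correlated with r = 0.807 and rho = 0.724 over 3822 genes. A set of 6 abundant rows that moved together, chosen after the values were seen, took 24.3% ± 3.0 (SD, n = 4) of all counts in AKS319 without glucose and 25.5% ± 4.5 (n = 2) in AKS133, against 10.2% ± 2.1 (n = 4) and 9.5% ± 4.6 (n = 3) in the parent libraries of those years. These rows were not identified, and whether their share reflects expression or ribosomal RNA left after its removal was not tested. Per the labels, the percent of read pairs mapped without glucose was 63.2 to 68.6 in AKS319 against 74 to 77.9 in the parent in 2022, while in 2021 it was 92.8 and 93.5 in AKS133 against 89.4 to 90.5 in the 3 used libraries of the parent. Under plain library totals in place of TMM factors, the median log2 fold change of all genes moved from 0.01 to -0.39, and the split became 409 higher and 1982 lower, so directions of small changes are relative to the scaling.

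With glucose, the mutants and the parent differed at 2 genes. pyrF was higher by 6.71 (SE 1.08, edgeR adjusted p = 0.00267) and HAH_RS07525 was lower, at -6.57 (SE 0.25, adjusted p = 5.91e-17). Among 3841 genes, 337 had an unadjusted p under 0.05, and DESeq2 called 3. The 95% interval of the fold change lay within 2-fold either way for 3674 genes, so larger changes were excluded for those. The genes that answered the deletion without glucose were close to the parent level here: of the 625 genes called at 2-fold or more without glucose, 563 had an interval within 2-fold with glucose. Their median absolute log2 change was 1.46 without glucose and 0.14 with it. The 2021 libraries called 2 genes and the 2022 libraries 3, of which 1 was shared with the calls above; pyrF was not called in 2022 (6.64, adjusted p = 0.433). The call of pyrF was also lost without the AKS319 libraries that held it (5.15, adjusted p = 0.291) and with a block for replicate letters (6.43, adjusted p = 0.078), which left 1 gene called.

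**Figure D3:**
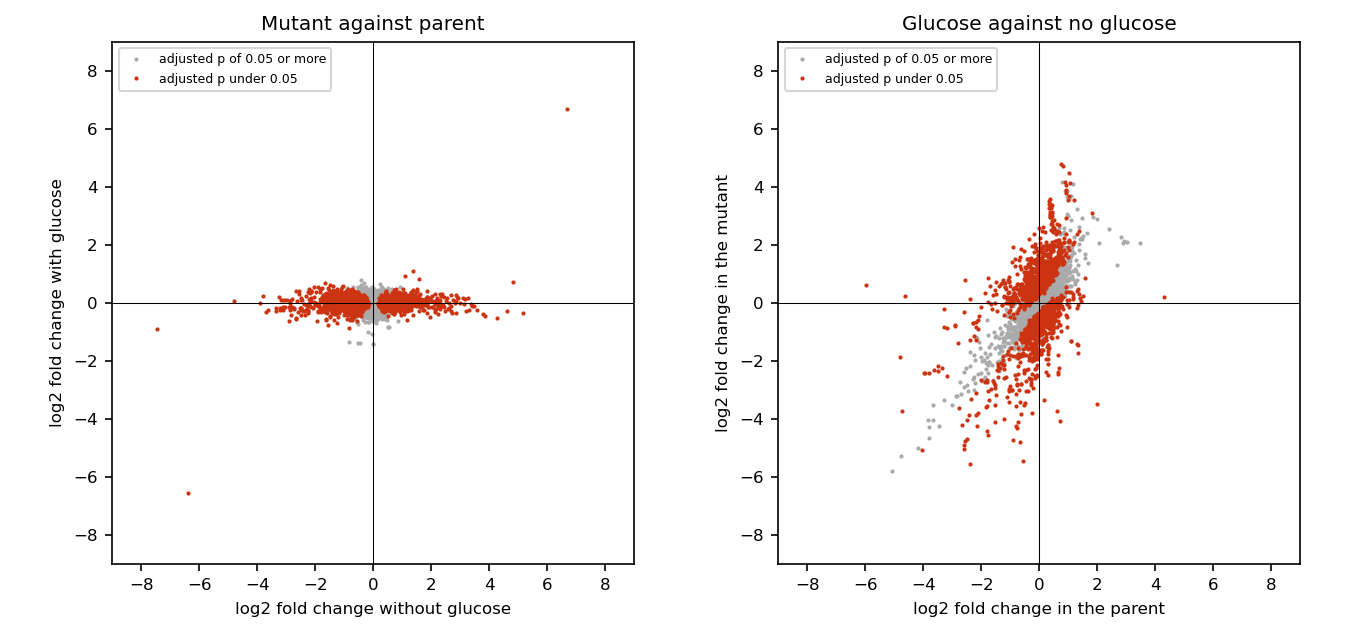
Log2 fold changes of 3841 genes. The left panel plots mutant against parent without glucose (horizontal) and with glucose (vertical), and red marks an adjusted p under 0.05 without glucose; the right panel plots the glucose response of the parent (horizontal) and of the mutants (vertical), and red marks an adjusted p under 0.05 for the difference of the responses. In the left panel nearly all genes lie along the horizontal line, and pyrF and HAH_RS07525 lie far from 0 on both axes.

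The response to glucose in the parent was examined next. HAH_RS06900 fell by 5.96 on the log2 scale with glucose (SE 0.23, edgeR adjusted p = 8.32e-17), to 30.3 ± 11.6 CPM in 2021 and 12.9 ± 0.93 CPM in 2022 (SD, n = 4 each). HAH_RS16740 fell by 5.09 (SE 0.26, adjusted p = 3.3e-14), from 22.5 ± 10.2 CPM (n = 3) to 0.70 ± 0.20 CPM (n = 4) in 2021 and from 54.4 ± 26.6 CPM to 1.5 ± 0.43 CPM (n = 4 each) in 2022. HAH_RS17930 rose by 4.32 (SE 0.33, adjusted p = 5.05e-11), from 13.7 ± 5.8 CPM (n = 3) to 479 ± 198 CPM (n = 4) in 2021 and from 23.0 ± 13.2 CPM to 312 ± 23.8 CPM (n = 4 each) in 2022. HAH_RS18175 rose by 3.49 (SE 0.82, adjusted p = 0.00138). Its rise was 2.06 without replicate D of the 2021 glucose group, which held 485 CPM against 10.3 to 15.6 CPM in the other 3 libraries.

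In the parent 1667 genes were called, 819 higher and 848 lower with glucose. Changes of at least 2-fold were more often falls (239 genes) than rises (89 genes), an imbalance that was larger in 2022 (290 falls, 64 rises) than in 2021 (243 falls, 221 rises). The 2021 libraries called 1616 genes (854 higher, 762 lower), of which 1091 were among the 1667. The 2022 libraries called 1898 (914 higher, 984 lower), of which 1276 were among them. Of the calls from both years together, 99.3% and 99.4% kept their sign in 2021 and 2022. With no batch term the number fell to 1093, of which 1087 were among the 1667.

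The response to glucose was then examined in the trmB mutants. HAH_RS16740 fell by 5.78 (SE 0.28, edgeR adjusted p = 1.34e-15), against a log2 change of -5.09 in the parent. The difference of these changes, -0.69, had a 95% interval of -1.44 to 0.05 (adjusted p = 0.124). HAH_RS00880 fell by 5.54 (SE 0.32, adjusted p = 6.6e-14), from 469 ± 91.6 CPM (n = 2) to 9.49 ± 1.91 CPM (n = 4) in AKS133 and from 134 ± 16.7 CPM to 4.48 ± 0.75 CPM (n = 4 each) in AKS319. HAH_RS16480 rose by 4.78 (SE 1.40, adjusted p = 0.00417) and HAH_RS16490 by 4.73 (SE 1.2, adjusted p = 0.00122). These 2 genes varied widely between libraries of a group. With glucose, HAH_RS16480 reached 1313 ± 153 CPM in AKS133 in 2021 but 17.3 ± 15.7 CPM in AKS319 in 2022 (SD, n = 4 each). The parent with glucose had a like gap between years, at 1000 ± 416 CPM in 2021 and 19.5 ± 19.7 CPM in 2022 (n = 4 each). Without replicate C or D of AKS133 without glucose, either of which leaves that group 1 library, the rise of HAH_RS16480 was 4.15 or 4.12 (adjusted p = 0.0137 and 0.0148), and over all alternatives it ran from 2.64 to 8.60. In 2022 alone HAH_RS16480 was not called (2.64, adjusted p = 0.0738).

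In the mutants 2553 genes were called, 1277 higher and 1276 lower with glucose, with 455 and 450 of them changed by at least 2-fold. The 2021 libraries called 2569 (1325 higher, 1244 lower), of which 1962 were among the 2553. The 2022 libraries called 2607 (1321 higher, 1286 lower), of which 2060 were among them. Of the calls from both years together, 93.6% and 96.9% kept their sign in 2021 and 2022. Under plain library totals the split was 2070 higher and 653 lower, with a median log2 change of 0.39 over all genes. The responses of the genotypes, which share no libraries, overlapped in 500 genes that rose in both and 522 that fell in both, where independent lists would share 272.3 and 281.7. A further 78 genes rose in the parent and fell in the mutants, and 109 did the reverse. Across genes, the log2 changes correlated with r = 0.596 (0.591 in 2021, 0.623 in 2022).

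The difference of the glucose responses was tested directly. Among the genes that met the naming rule, HAH_RS06900 had the largest positive difference, 6.57 (SE 0.31, edgeR adjusted p = 1.49e-14): glucose lowered it in the parent, while in the mutants it was low in both media and rose by 0.61 (SE 0.22, adjusted p = 0.0159). HAH_RS19805 differed by 4.86 (SE 0.40, adjusted p = 2.67e-10), with 583 ± 70.2 CPM in DF60 without glucose and 17.4 ± 2.9, 16.1 ± 2.1 and 18 ± 3.3 CPM in DF60 with glucose, AKS319 with glucose and AKS319 without it in 2022 (SD, n = 4 each). In 2021 HAH_RS19805 stood at 970 ± 218 CPM (n = 3) in DF60 and 14.3 ± 1.6 CPM (n = 2) in AKS133 without glucose. With glucose it stood at 54.0 ± 10.9 and 60.9 ± 15.9 CPM (n = 4 each) in DF60 and AKS133 in 2021. In the fits of each year, its log2 change with glucose was 1.80 in AKS133 and -0.56 in AKS319. These fits use scaling factors, which the CPM values do not. HAH_RS04465 had the largest negative difference among them, -5.51 (SE 0.48, adjusted p = 8.19e-10). It rose with glucose by 2.00 (SE 0.33) in the parent and fell by 3.50 (SE 0.34) in the mutants. HAH_RS12790 differed by -4.89 (SE 0.33, adjusted p = 6.08e-12), with 665 ± 219 CPM in AKS319 without glucose against 23.0 ± 4.2 CPM with it (SD, n = 4 each), and a change of -0.57 (SE 0.22) in the parent.

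**Figure D4:**
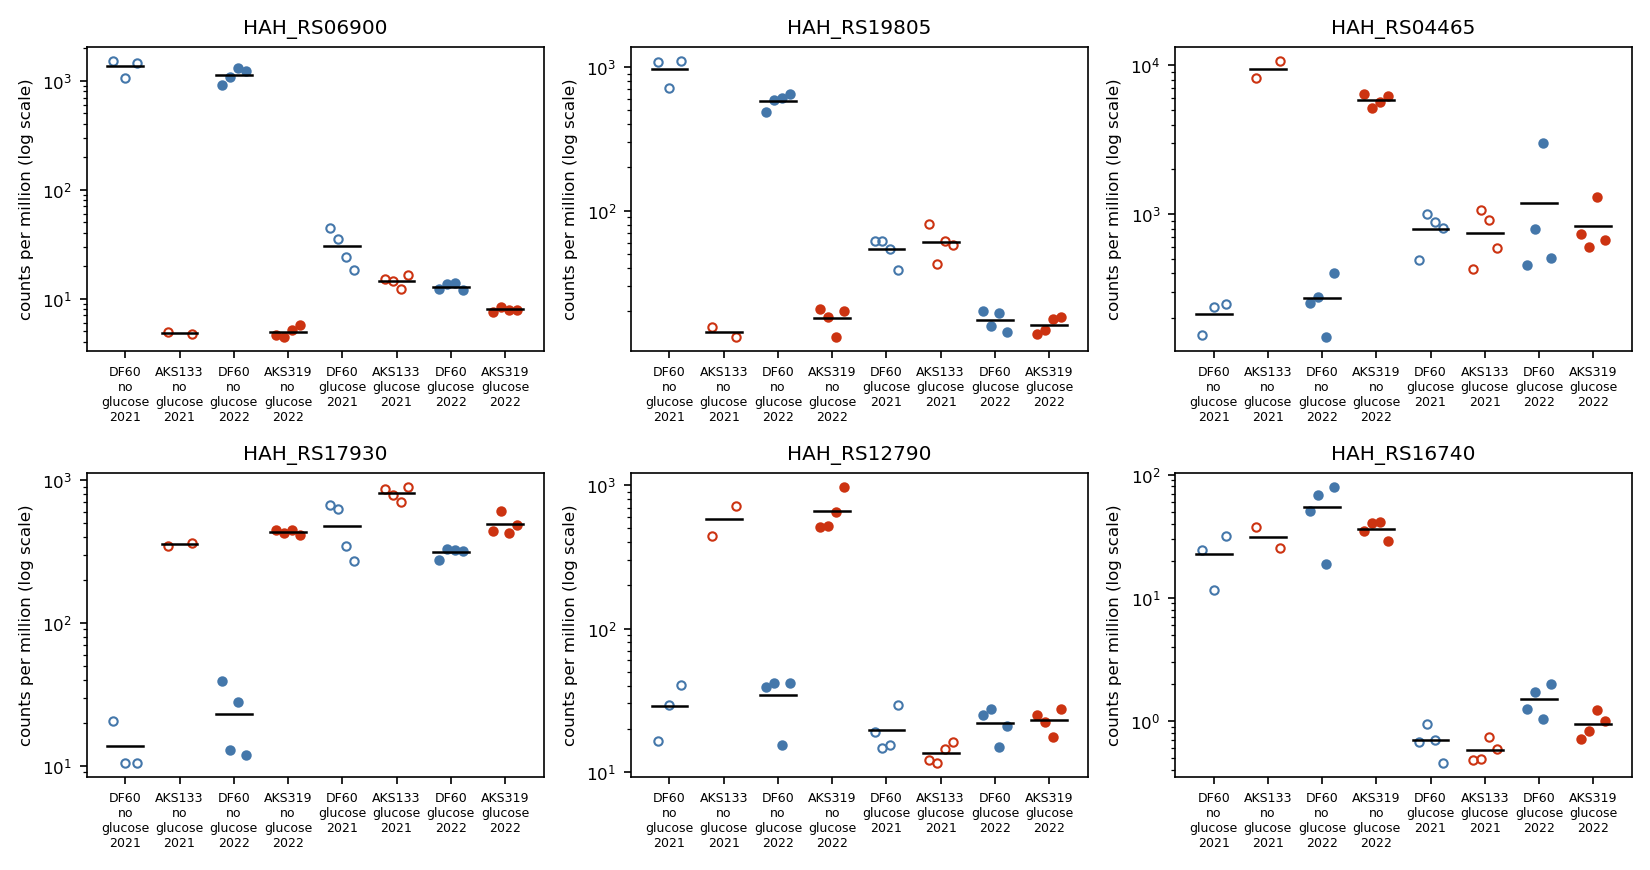
CPM values of 6 named genes in each of the 29 analysed libraries on log axes, by strain, medium and year; open circles are 2021, filled circles 2022, blue the parent, red the mutants, and bars are group means. HAH_RS06900 and HAH_RS19805 are high in the parent without glucose, HAH_RS04465 and HAH_RS12790 in the mutants without glucose, HAH_RS17930 is low in the parent without glucose, and HAH_RS16740 is high in both genotypes without glucose.

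The difference was called for 1707 genes, with a more positive response in the mutants for 864 and a more negative one for 843. Of these, 897 responded to glucose by the test in the mutants and not in the parent, 211 in the parent and not in the mutants, 371 in both in the same direction and 187 in both in opposite directions. The remaining 41 were called in neither genotype alone. The 2021 libraries called 1875 genes (934 positive, 941 negative), of which 1317 were among the 1707. The 2022 libraries called 1657 (872 positive, 785 negative), of which 1351 were among them. Of the calls from both years together, 98.8% and 99.9% kept their sign in 2021 and 2022. A block for replicate letters lowered the number to 1112. Plain library totals gave 1712 positive and 306 negative differences, with a median of 0.38 over all genes.

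**Figure D5:**
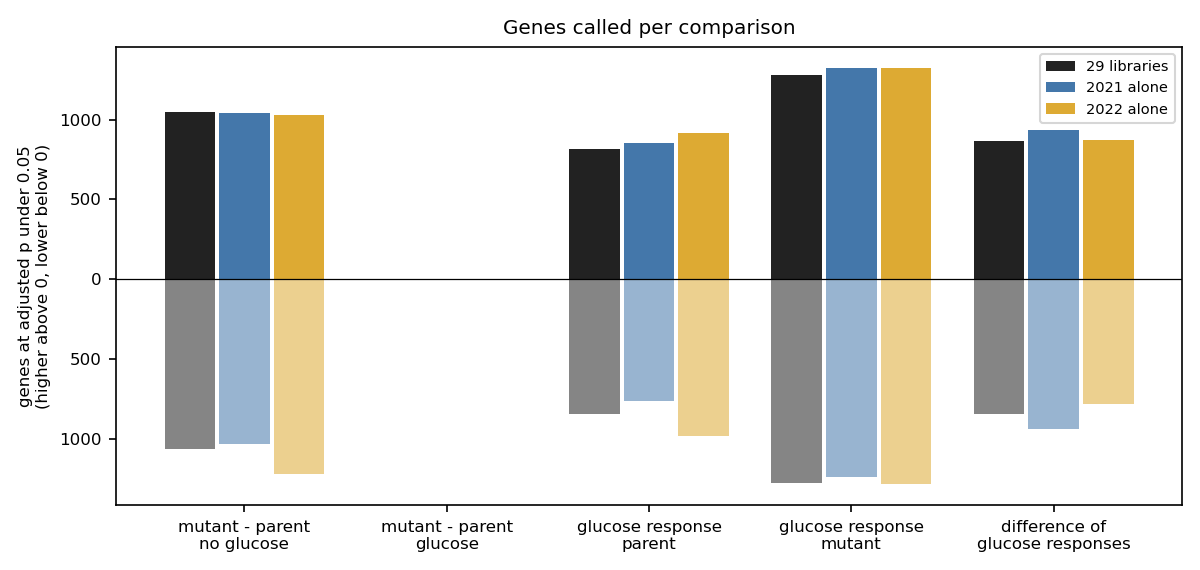
Number of genes at an adjusted p under 0.05 in each of the 5 comparisons, higher above 0 and lower below it, for all 29 libraries and for each year alone. Mutant against parent gives 2113 genes without glucose and 2 with glucose.

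The effect of the deletion was then compared between the mutant strains, each against the parent libraries of its own year. Without glucose, HAH_RS05550 had a more positive effect in AKS133 by 4.56 (SE 1.2, edgeR adjusted p = 0.00769) and HAH_RS05540 by 3.94 (SE 1.17, adjusted p = 0.0165). The size of these differences was unstable: across the alternatives it ran from 4.08 to 8.15 and from 3.42 to 7.45, with the highest values under a block for replicate letters, and without replicate A of DF60 without glucose in 2021 it was 6.00 and 5.43. Within the years, the log2 fold change of mutant against parent was 0.49 in 2021 and -4.10 in 2022 for HAH_RS05550, and 0.23 and -3.74 for HAH_RS05540. HAH_RS05550 stood at 162 ± 147 CPM (n = 3) in DF60 and 182 ± 66.8 CPM (n = 2) in AKS133, and at 1878 ± 1062 CPM in DF60 and 86.3 ± 11.9 CPM in AKS319 (SD, n = 4 each). HAH_RS06130 had a more negative effect in AKS133 by -3.21 (SE 0.78, adjusted p = 0.00437) and HAH_RS06125 by -3.18 (SE 0.80, adjusted p = 0.0054), with -0.86 in 2021 and 2.34 in 2022 for the former. In AKS319 without glucose, HAH_RS06130 stood at 428 to 581 CPM in replicates A to C but at 57.3 CPM in D. HAH_RS06125 stood there at 188 to 263 CPM in A to C but at 25.2 CPM in D. In all 1041 genes differed without glucose, 545 more positive and 496 more negative in AKS133. With glucose 0 genes differed in edgeR and 0 in DESeq2, and 472 had an unadjusted p under 0.05, while edgeR with a block for replicate letters called 82. AKS133 without glucose had 2 libraries: without its replicate D the count was 626 and HAH_RS05540 was not called (3.57, adjusted p = 0.0659). HAH_RS05540 also lost its call without the AKS319 libraries that held pyrF (4.06, adjusted p = 0.0597). Without replicate A of DF60 with glucose in 2021, the count with glucose rose from 0 to 213.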

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

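The tests of scaling, of mapped read pairs, of mixed cells, of carry-over between libraries (with bounds set when the pyrF levels were known), and of pairs of libraries of like depth were chosen only after the results were seen, as were the set of 24 genes and the 6 abundant rows. The other tests in this part were fixed before their own results were seen. A further test set down then, of the year difference in the parent against that in the reference RNA, was not run.

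Without glucose, mutant and parent differed at 2113 genes. None of the other 99 splits of the 13 libraries gave as many, with 1621 genes at most in a split that moved 2 libraries, so 1 of 100 splits reached the real count. A single scaling factor per library would push calls of 2-fold or more to one side, yet at least 147 lay in the smaller direction under each of 3 scalings, and 2114 genes were called without the 6 abundant rows. Those rows may be ribosomal RNA left after depletion, in which case their share would measure depletion rather than expression, but they could not be identified here. A flowcell set against genotype in 2021 is argued against by 2253 calls in 2022, where all libraries ran on the same flowcell, and pyrF transcripts by 1746 calls with a term for the libraries that held them. The lower percent of mapped read pairs in the mutant in 2022 is argued against as the whole cause by 2077 calls in 2021, where it was higher in the mutant (92.8 and 93.5 against 89.4 to 90.5 in the used parent libraries) and the log2 fold changes correlated with those of 2022 (r = 0.807 across genes). A state of growth at harvest that differs between mutant and parent without glucose was not tested and stays open, as does an effect of trmB itself.

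The other counts were set against splits in the same way. With glucose, 2 of 100 splits of the 16 libraries gave 2 genes or more, the real one included, and the highest other gave 493, which points to a structure of the samples that was not identified. For the glucose response of the parent the real count of 1667 was reached in 1 of 100 splits (highest other 637), and for that of the mutants the count of 2553 in 1 of 100 (highest other 2169, a split that is the mirror of the real one except for 2 libraries). The difference of the responses, 1707 genes, was reached in 1 of 100 (highest other 984). The share of splits that reached the real count was under 0.05 for the glucose responses of the parent and of the mutants and for their difference. Apart from those for the mutant strains, all splits moved labels across years, which also separated the libraries. They therefore cannot exclude chance among libraries of the same year. For the difference, genotype was relabelled within each medium, so those splits speak to any effect of genotype and not to the difference alone. For mutant against parent with glucose, the real count was pyrF and HAH_RS07525 alone, so its share speaks only to those 2 rows. For the comparison of the mutant strains with glucose, 0 genes were called, a count that each of the 100 splits must reach, so the splits say nothing about chance there; the highest other gave 6.

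The glucose response differed between genotypes at 1707 genes by the test of the difference, and the effect of the deletion differed between AKS133 and AKS319 at 1041 genes without glucose. In the second case strain and year cannot be told apart.

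pyrF was high in 10 mutant libraries that are labelled as lacking it, and the unused DF70 reference libraries held 193 and 202 CPM against 4.91 CPM at most in the parent. Cells with pyrF and trmB mixed into the cultures may have been a source, but they would carry HAH_RS07525 too if that row is trmB, and in those 10 libraries its share of the reference level was at most 0.0125 of the pyrF share. Fragments carried over from another library of the flowcell would leave a library below that one. On the 2022 flowcell this is argued against, since the lowest of the 4 high mutant libraries held 1.58 times the CPM of the DF70 reference, the highest of the 13 other libraries, and 106 times that of the highest of the 12 low ones; carry-over among those 4 would still leave at least 1 with pyrF of its own. A first bound, over 100-fold between all high and all low libraries of that flowcell, was missed with the reference counted as high (67.4). On the 2021 flowcell SP it is argued against too, since the AKS133 library there held 114 times the CPM of the highest other library. On the 2021 flowcell S1 the ratios of the 5 AKS133 libraries to the reference library were 0.342, 1.03, 1.05, 2.04 and 3.04. Of these, 3 lay above 1 by more than the 95% counting interval. The other libraries outside AKS133 on that flowcell held 3.95 CPM of pyrF at most. Carry-over from the reference library would bring HAH_RS07525 in the same share as pyrF. The 2 libraries at 0.342 and 1.03 held 33.3% and 100.8% of the reference level of pyrF. They held 0.34% and 0.96% of that of HAH_RS07525, which argues against such carry-over for them. Carry-over among the AKS133 libraries stays open there. A pyrF copy kept in or returned to part of the mutant cultures is a hypothesis that was not tested.

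Of 32 genes with a within-group SD of at least 1 on the log2 scale, 24 formed a set that rose and fell together between single libraries (median r = 0.96 across genes). The set included HAH_RS16480 and HAH_RS16490, named above for their rise with glucose in the mutants. Of its 24 genes, 24 were called for glucose in the mutants, 17 for the deletion without glucose and 1 for glucose in the parent. Over all genes tested, these calls made up 66.5%, 55% and 43.4%. With glucose, the set's mean log2 CPM in 2021 was 10.2 to 10.61 in the parent and 10.32 to 10.47 in AKS133. In 2022 it was 5.91 to 8.46 in the parent and 5.78 to 8.76 in AKS319. Without glucose it was 4.01 and 4.39 in AKS133 and 5.23 to 5.85 in AKS319. In the parent without glucose in 2021 it was 9.58 in the library lettered C, against 4.47 and 4.84 in the other 2. In 2022 it was 9.46 in the one lettered C, against 5.46 to 6.66. These lettered C libraries entered the parent level, so the 1 call there does not show a rise limited to the mutants. RNA of a glucose culture mixed into these libraries would move other genes raised by glucose by the same share, but their median move was at most 2.6% of the way, against 61% and 412.5% for the set. Depth is argued against by a difference of 5.11 between libraries of a group 1.11-fold apart in total count, in a test added after the planned one. The planned correlation with total count within groups, over 29 libraries, had r = 0.264 (permutation p = 0.3), rho = 0.225 (p = 0.307) and r = 0.277 without the 2 libraries farthest from the median, and by itself a p of this size excludes nothing; no biological explanation was tested.

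Among 146 sets of 4 libraries examined over 21 measures, 15 held a library far from the others, where chance gives about 7.3 at a share of 0.05. The measures included the mean of the set of 24 genes and its members HAH_RS16480 and HAH_RS16490. That set was chosen for its spread within groups, so the chance figure does not hold for these measures. In the parent without glucose in 2021, the unused replicate B had 59.43% of its counts in its 10 highest rows and 54.03% in the 6 abundant rows, against 25.85% and 14.81% at most in the others. Replicate A with glucose in 2021 had the lowest total count of its group, 26557969, and replicate C the lowest share of the 6 rows, 5.19%. In AKS319 with glucose, replicate B had the lowest total count, 20630325. HAH_RS04465 reached 2994 CPM in replicate C of the parent with glucose in 2022, HAH_RS17930 20.4 CPM in replicate C of the parent without glucose in 2021, and HAH_RS18175 485 CPM in replicate D of the parent with glucose in 2021. In replicate C of the parent without glucose in 2022, HAH_RS16480 stood at 107 CPM, HAH_RS16490 at 1802 CPM and HAH_RS12790, the lowest of its group, at 15.4 CPM. In AKS319 without glucose, HAH_RS16490 stood at 41.2 CPM and the mean of the set of 24 genes at 5.85 in replicate D, and HAH_RS05550 at 103.9 CPM in replicate B. HAH_RS06130 was lowest, at 28.2 CPM, in replicate A of the parent with glucose in 2022.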

How the results depend on the processing

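Plain library totals, leaving out the parent libraries lettered C without glucose, and leaving out the 6 abundant rows were chosen after the data were seen. Of 288 recomputed counts of genes, 278 stayed within 1.5 times the reported ones. The 288 include the fits that leave out each library in turn, and the measure compares numbers alone, not which genes were called. Under plain library totals, 2391 genes were called for mutant against parent without glucose, of which 1477 were among the 2113. Of 922 recomputed log2 fold changes of named genes, 913 kept their direction and side of the threshold, 7 lost their call and 2 changed sign. The glucose response of the parent fell from 1667 to 1093 genes with no batch term. For mutant against parent with glucose, 1 gene was left without the AKS319 libraries that held pyrF and 1 with a term for such libraries. Without pyrF, HAH_RS07525 and the rows next to them 0 genes were left, because both called rows were removed. The difference between mutant strains with glucose gave 1 gene without those AKS319 libraries. With the pyrF term the log2 fold change of pyrF became -0.398 without glucose and -0.648 with it, since the term itself takes up pyrF (7.75, SE 0.47). The cause of the other changes was not tested. Without the lettered C libraries the 5 counts were 1986, 2, 1411, 2538 and 1564, and without the 6 abundant rows 2114, 2, 1671, 2543 and 1693.

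Leaving out each of the 29 libraries gave 2002 to 2150 genes for mutant against parent without glucose, 2 to 3 with glucose, 1444 to 1784 for glucose in the parent, 2446 to 2581 in the mutants and 1592 to 1761 for the difference. Between mutant strains it gave 626 to 1187 genes without glucose, where leaving out replicate D of AKS133 left a lone library assumed to vary like the other groups, and 0 to 213 with glucose.

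Libraries with a replicate letter in common mostly did not deviate together. Of 13 such pairs across media, 3 correlated above 0.1 in their deviations from group means (-0.13 to 0.47), and 3 correlated best with their own letter. So few pairs cannot show by correlation whether the letters pair the samples, which stays open for most letters. In AKS319 with glucose, pyrF had 50 counts in C and 11180 in D, but without glucose 5077 in C and 36 in D. This argues against letters C and D of AKS319 marking the same cells in both media, unless pyrF changed within them or samples were swapped. A block for the letters gave 1 gene for mutant against parent with glucose, 1112 for the difference of the glucose responses and 82 between mutant strains with glucose, and no other count moved by over 1.5 times. For mutant against parent and between mutant strains, the block joined parent and mutant libraries of like letter, a pairing that the labels do not give. Under the block pyrF with glucose (6.43, adjusted p = 0.078) and HAH_RS16480 for glucose in the mutants (4.06, adjusted p = 0.0548, edgeR) were not called. The list tests and their estimated correlation were not run, since list members could not be matched. Total counts were 12719797 or more in each library. At the simulated spread, 1.5-fold changes were mostly missed in the difference of responses.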

Other observations

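The tests in this part were chosen only after the data were seen, and both concern the order and overlap of calls. Genes that changed together often lay in neighbouring rows of the table. For mutant against parent without glucose, 936 of 3822 pairs of adjacent rows were called in the same direction, against 577.7 on average and 644 at most in 10000 shuffles of the rows. There were 59 runs of at least 5 adjacent calls in a single direction, the longest of 25 rows. For glucose against no glucose, 767 pairs (shuffled mean 359.7) were found in the parent and 1327 (844) in the mutants, with longest runs of 38 and 59 rows. The log2 changes of adjacent rows correlated with r = 0.435 for the deletion without glucose and 0.57 and 0.542 for glucose in parent and mutants. Row order is that of the deposited table and was not compared with a genome.

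The genes that glucose changed in the parent lay on both sides of the parent level in the mutants without glucose. Of 239 genes that fell by at least 2-fold with glucose in the parent, 78 were lower in the mutants without glucose, 60 were higher and 101 were not called. Of 89 that rose, 22 were higher, 21 lower and 46 not called. These comparisons share the 7 parent libraries without glucose. Their log2 changes had a correlation of 0.016 and a covariance of 0.01 across genes. In 20 simulations of unchanged groups, the mean correlation was 0.49 and the mean covariance 0.019. The simulated changes were noise alone, so the correlations cannot be compared, and only the covariances can. Among all calls, 192 genes were higher in both comparisons and 258 lower in both, against 223.7 and 234.9 for independent lists. The simulations gave 0 calls in either comparison, so they say nothing about shared calls. With the controls split by year, the correlation was 0.102 for the deletion in 2021 and glucose in 2022, and -0.062 for the reverse.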
